A study of Mus musculus with 3 samples.

How the data were processed

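The data were 3 one-colour Agilent whole mouse genome arrays, 1 for each of 3 groups, all on 1 slide and scanned on 1 day. Groups were taken from the sample labels: untreated C2C12 myoblasts, cellulates given BIO, and cellulates given BIO and then neurogenic medium. Per the labels, 200 ng of total RNA was amplified and labelled with Cy3. The sources give conflicting doses. The sample labels state 2.5 µM BIO for 2 days, whereas the series text and the treatment protocol state 10 µM, and myoseverin is given as 20 µM for 48 h in the series text and as 30 µM in the treatment protocol. Per the series text, myotubes were formed for 8 days in 2% horse serum, with 10 µM AraC from day 2 to day 4 against remaining myoblasts, and BIO followed 24 h after myoseverin. Per the labels' protocols, the neurogenic culture received 250 nM reversine for 48 h, DMEM/F12 with N2 supplement, and 1.5 µM all-trans retinoic acid for 7 days. No array of untreated myotubes or of cellulates without BIO was analysed here, so differentiation, AraC, myoseverin and BIO cannot be separated in the first comparison, nor medium, reversine, retinoic acid and time in the second. Nothing in the sources says how many cultures stand behind each array.

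Per the file headers, Agilent Feature Extraction 10.7.3.1 read array design 014868 and wrote, for each spot, a linear intensity after background subtraction and detrending, along with median pixel intensities of the spot and its background. The genome build named in those headers is mm9. The authors' deposited table of processed values is on the log2 scale: set against the scanner intensities of probes with a single spot, each column equals the log2 intensity plus a constant of 0.00, 0.67 and 0.23 for myoblasts, BIO cellulates and neurogenic cellulates. These constants lie close to the differences in log2 75th percentile from the myoblast array, 0.00, 0.66 and 0.22; why they are not equal to them is unknown. The deposited columns are not centred by gene, hold values almost only for probes well above background (20738 of 20765, 19179 of 19192 and 18587 of 18592 values), and have medians of 7.42, 7.77 and 7.88. The number of columns of other samples was 0.

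Spots of control probes and spots marked as outliers were left out, and spots of a probe were averaged on the log2 scale. Each array's value was the log2 processed intensity minus the log2 of its 75th percentile over non-control spots, which was 181, 115 and 156 intensity units for myoblasts, BIO cellulates and neurogenic cellulates. Median intensities were 17.1, 17.9 and 24.4, and the lowest intensities called well above background were 13.6, 17.3 and 26.2. Scaling to the array median, an alternative used below, therefore rests on signal near background. Of 41174 non-control probes, 26918 were named by matching their accession, without version, to the RefSeq gene table of assembly GRCm38.p6, and 14256 stayed unnamed. Because the headers name another build, no coordinates are given. The named probes covered 18350 genes, 6530 of them with more than 1 probe. A gene took the probe with the highest mean over the 3 arrays. Among genes with several probes well above background on both arrays compared, probes were at least 2-fold different in opposite directions for 11 genes in BIO cellulates against myoblasts, 0 in neurogenic against BIO cellulates and 17 in neurogenic cellulates against myoblasts. Some genes at least 2-fold different had another probe well above background on at least 1 of the 2 arrays. The brightest such probe passed 2-fold the same way in 52.7% of higher and 57.2% of lower genes in the first of these comparisons. It passed the opposite way for 5 of 184 and 8 of 236 there, 0 of 85 and 2 of 53 in the second, and 7 of 247 and 32 of 441 in the third.

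A gene was measured on an array when its probe was well above background. Where a gene was measured on 1 of the 2 arrays compared, the fold is a lower bound, the measured signal over the higher of the dim probe's own signal and the lowest signal well above background on the dim array. A bound below 1-fold was set to a log2 ratio of 0, which gave some list medians of 0.00. Genes whose probes disagreed on background were left out of the counts (69, 45 and 82 genes in the 3 comparisons), as were genes measured on neither array (5450, 6048 and 5411). Bounds supplied 497 of the higher and 85 of the lower genes in the first comparison, 244 and 67 in the second, and 539 and 92 in the third. These numbers follow largely from the arrays' lowest signals well above background, which after scaling lay at -3.73, -2.73 and -2.57 on the log2 scale for myoblasts, BIO cellulates and neurogenic cellulates. A gene measured on a cellulate array alone therefore passes 2-fold against myoblasts almost by construction, as 497 of 498 and 539 of 539 did, whereas 85 of 1146 and 92 of 1431 measured in myoblasts alone passed. Genes measured on neither array had median log2 ratios of 1.01, 0.12 and 1.14, so a dim gene near 2-fold against myoblasts carries little weight. With 1 array per group there are no residual degrees of freedom, so genes were counted at a 2-fold threshold and no test was made.

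The lists and rules were fixed before the data were examined. There were 28 gene lists: cell cycle, CDK inhibitors and pocket proteins, p53 targets, myoblast and satellite cell markers, terminal muscle differentiation, Wnt and beta-catenin targets, aryl hydrocarbon receptor targets, retinoic acid targets, neurons, neural progenitors and proneural factors, glia, Notch pathway, extracellular matrix and mesenchyme, adipocytes, osteoblasts, chondrocytes, pluripotency, cholesterol synthesis, unfolded protein and amino acid response, interferon-stimulated genes, inflammatory cytokines and chemokines, hypoxia and glycolysis, oxidative phosphorylation, tubulins, ribosomal proteins, endothelial cells, macrophages and leukocytes, and epithelial cells. For each list with at least 5 measured members, the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean signal, and a list was called higher or lower outside the middle 95%. This describes these arrays and is not a p-value. The text names 26 key genes whatever their values, the 8 largest differences each way among genes measured on both arrays, the 3 largest bounds each way, and up to 4 members of each list at least 2-fold different, leaving out clone, predicted and unnamed symbols and, where a list lay inside the middle 95%, some of its members. Some genes that this rule takes are not reported here.

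The calculations were tested on simulated arrays made from the real signals and spot noise. Both arrays of a simulated comparison started from the signals and background calls of 1 real array. Changed genes were drawn only from signals clearly above the lowest signal well above background. The simulations therefore leave out differences in lowest signal between arrays, dim changed genes, and culture, RNA and labelling differences. In BIO cellulates against myoblasts, with 12341 genes, 4 of 50 genes changed 1.5-fold passed the 2-fold threshold, 27 of 50 at 2-fold, 50 of 50 at 3-fold and 50 of 50 at 4-fold, with 1 of 12078 unchanged genes passing. In neurogenic against BIO cellulates, with 11704 genes, the numbers were 2, 26, 49 and 50 of 50, and 0 of 11443. In neurogenic cellulates against myoblasts, with 12341 genes, they were 0, 28, 50 and 50 of 50, and 1 of 12078. Lists with no changed gene lay outside the middle 95% in 16 of 270, 8 of 260 and 19 of 270 cases. A list shifted by -1 on the log2 scale returned -1.01, -1.04 and -0.84.

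Alternatives were scaling to the array median, to the 75th percentile over probes well above background on all 3 arrays, and to 8 spike-in control probes, quantile normalisation, normexp background correction with an offset of 50, the authors' deposited log2 values, no filter on dim probes, only genes measured on both arrays, the median over a gene's probes, a 3-fold threshold, and unmatched random lists. The normexp correction planned on mean spot signals used median spot signals instead, because the mean signal is not among the columns used here. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 were used.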

Results

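Gene expression was measured in 3 cultures derived from C2C12, a mouse myoblast line that fuses into multinucleated myotubes when serum is reduced. One-colour Agilent whole mouse genome arrays were hybridised with Cy3-labelled RNA, with 1 array per group. The first culture was untreated myoblasts. The second, called BIO cellulates here, came from myotubes that had been taken apart into cellulates with myoseverin, a compound that binds microtubules, and then exposed for 2 days to BIO, the GSK-3 inhibitor 6-bromoindirubin-3'-oxime. The third, called neurogenic cellulates here, was BIO cellulates kept for 7 more days in neurogenic medium. There were no replicates, so no difference has an error between cultures or a p-value, and the number of arrays limits the precision of every value. Of 43379 non-control spots on each array, 22014 (50.7%) were well above background for myoblasts, 20358 (46.9%) for BIO cellulates and 19812 (45.7%) for neurogenic cellulates, and none was saturated. Probes spotted 10 times gave the only repeat measure, within an array: 95% of differences between single spots would lie within 1.45-fold for BIO cellulates against myoblasts, 1.36-fold for neurogenic against BIO cellulates and 1.41-fold for neurogenic cellulates against myoblasts. Folds below are ratios of signals scaled to each array's 75th percentile, and "at least" marks a gene that was well above background on 1 of the 2 arrays compared. Myf5, Axin2, Cyp1a1, Cyp1b1, Sox2, Neurod1 and Nefl were not well above background on any array, and Ccnd1 had no probe that could be named.

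The first comparison asked how BIO cellulates differed from the myoblasts they ultimately came from. BIO cellulates had more RNA of terminal muscle differentiation genes, and less RNA of genes for cell division, sterol synthesis and extracellular matrix. Ckmt2, the mitochondrial creatine kinase of striated muscle, was 2174-fold higher, and the fast troponin T gene Tnnt3 was 119-fold higher. The mitotic cyclin gene Ccnb1 was 10.6-fold lower and the proliferation marker Mki67 was 7.80-fold lower. Of 12829 genes compared, 1440 were at least 2-fold higher in BIO cellulates and 771 at least 2-fold lower, or 943 and 686 among genes measured on both arrays, since a bound passes 2-fold far more easily on the higher side.

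Genes of terminal muscle differentiation had a median of 2.28 on the log2 scale, with 44 of 63 measured members at least 2-fold higher and 0 lower. Skeletal actin Acta1 was 55.0-fold higher, muscle creatine kinase Ckm 49.0-fold, the muscle glycogen phosphorylase gene Pygm 49.2-fold and embryonic myosin heavy chain Myh3 30.1-fold. The myosin light chain gene Myl3 was 162-fold higher by its brighter probe, whereas its second probe gave a log2 ratio of 0.70. Outside this group, the regulator of the calcium pump sarcolipin (Sln) was 60.5-fold higher, Mustn1 103-fold, the steroid-converting enzyme gene Akr1c18 139-fold and the muscle subunit of cytochrome c oxidase Cox6a2 65.0-fold. Myo18b, an unconventional myosin gene, was at least 115-fold higher, the muscle AMP deaminase gene Ampd1 at least 74.9-fold and the actin filament nucleator gene Lmod2 at least 32.6-fold. The myogenic regulators differed less, with log2 ratios of 0.36 for Myod1, 0.31 for Myog and 0.74 for Pax7.

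Cell-cycle genes had a median log2 ratio of -2.07, or -1.36 with the median over a gene's probes. Of 40 measured members, 31 were at least 2-fold lower. The spindle checkpoint kinase gene Bub1b was 8.37-fold lower, the mitotic kinase gene Plk1 8.10-fold and Cdk1, the kinase that drives entry into mitosis, 6.34-fold. The 1 member at least 2-fold higher was Nuf2, a kinetochore gene chosen after its values were seen, with a log2 ratio of 1.30. Other division genes among the lowest were Cenpw (9.75-fold), the securin gene Pttg1 (9.18-fold), Tacc3 (8.64-fold), Knstrn (8.46-fold) and the condensin gene Ncapg (at least 12.4-fold). The cell-cycle inhibitor gene Cdkn1a had a log2 ratio of 0.72. Tmem59 was 22.2-fold lower and Emsy 12.2-fold lower, and Tmem251 at least 11.4-fold lower, on the BIO array alone: neurogenic cellulates had log2 ratios to myoblasts of 0.02, -0.07 and 0.61 for these genes. The annexin gene Anxa8 was 10.2-fold lower and the EGF receptor ligand gene Areg at least 10.5-fold lower.

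Genes of cholesterol synthesis had a median log2 ratio of -0.98, with 10 of 23 at least 2-fold lower and 0 higher. Dhcr7, which encodes a reductase at the end of the pathway, was 6.64-fold lower and the sterol transfer gene Stard4 at least 4.68-fold lower. Extracellular matrix and mesenchyme genes had a median of -0.66, with 14 of 40 at least 2-fold lower, among them fibulin Fbln1 (4.10-fold), periostin Postn (3.52-fold) and thrombospondin Thbs1 (3.43-fold). The protease inhibitor gene Timp3, 1 of 3 members at least 2-fold higher, was 4.13-fold higher. Tubulin genes had a median of -0.72, with 3 of 12 at least 2-fold lower, namely Tuba1c (2.14-fold), Tuba1a (2.06-fold) and Tubb4b (2.00-fold). Notch pathway genes had a median of -0.49, which turned to 0.008 without the filter on dim probes, and the list lay inside the middle 95% of random lists there and after normexp correction. Among 13 measured Notch members, the receptor gene Notch3 (2.39-fold) and the feedback inhibitor gene Nrarp (2.35-fold) were among 4 at least 2-fold lower, while the ligand genes Dll1 (5.56-fold) and Dll4 (3.31-fold) were higher.

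Interferon-stimulated genes were higher as a group, with a median log2 ratio of 1.12, 9 of 16 at least 2-fold higher and 1 lower. Usp18, which removes the ubiquitin-like ISG15 protein, was 28.7-fold higher, Isg15 itself 11.9-fold, the antiviral gene Rsad2 3.22-fold and the RNA sensor gene Ifih1 at least 3.51-fold. The unfolded protein and amino acid response list had a median of 0.30, which turned to -0.42 with each array scaled to its median, and its stress transcription factor genes Atf3 and Ddit3 were 4.34-fold and 2.68-fold higher. In that list 5 of 26 members were at least 2-fold higher, including Ppp1r15a (2.48-fold), and the chaperone gene Pdia4 was 2.49-fold lower. Hypoxia and glycolysis genes had a median of 0.46, or -0.26 with median scaling, and 5 of 26 were at least 2-fold higher, including the glucose transporter gene Slc2a1 (2.87-fold), the angiogenic factor gene Vegfa (2.69-fold), Ankrd37 (log2 ratio 1.31) and Adm (2.23-fold). Oxidative phosphorylation genes had a median of 0.38, or -0.34 with median scaling, and 3 of 47 were at least 2-fold higher: Cox6a2, Ndufb5 (at least 8.86-fold) and Cox8b (at least 3.21-fold).

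Wnt targets, neuronal genes, neural progenitor genes and glial genes lay inside the middle 95% of random lists, the neuronal genes narrowly. Targets of Wnt and beta-catenin, the pathway that GSK-3 restrains, had a median log2 ratio of 0.00 over 21 genes, set by genes too close to background to give a fold. The median was 0.20 over the 18 measured on both arrays. Rnf43 (7.46-fold), Nkd2 (4.34-fold) and Ccn5 (2.52-fold, by a probe near background in myoblasts) were higher. Ccn4 (2.83-fold) and the transcription factor gene Lef1 (2.50-fold) were lower. Of 4 measured aryl hydrocarbon receptor targets, too few for a percentile, Gsta1 was 9.61-fold higher. Cyp1a2 gave a log2 ratio of 1.10 by a probe near background in myoblasts and 0.34 by a dim probe, while the 5450 genes dim on both arrays had a median of 1.01. Neuronal genes had a median of 0.36 over 35 genes, with 10 at least 2-fold higher and 4 lower. Camk2a was 4.13-fold and the migrating-neuron gene Dcx at least 3.82-fold higher. Vamp2 was 5.08-fold higher by its brightest probe, with log2 ratios of 2.06 and -0.52 by its other probes. The dendritic gene Map2 was 4.21-fold lower. Other neural genes had log2 ratios of 0.79 for Nes, -0.55 for Neurog1, -0.72 for Tubb3 and 0.88 for Gfap, and Rarb was not well above background on either array. The Gfap probe was near background on both arrays, and its ratio was below the median of 1.01 over genes dim on both. Cyp26a1 was well above background in myoblasts alone, at a signal too close to background to give a fold.

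The share of higher genes depended on the scaling and on brightness. Of the genes at least 2-fold different, 65.1% were higher in BIO cellulates, against 9.1% with median scaling, 76.9% with the percentile taken over probes well above background, 50.4% after quantile normalisation, 29.1% after normexp correction, 81.0% with no filter on dim probes and 57.9% among genes measured on both arrays.

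Further members of the small groups, chosen after their values were seen, had log2 ratios of 1.09 for Col3a1 and a bound of 1.19 for Tnc (matrix), -1.12 for Hes1 and -1.10 for Notch1 (Notch), 1.11 for Trib3 and 1.02 for Asns (amino acid response), and 1.10 for Hk2 and -1.04 for P4ha2 (hypoxia and glycolysis).

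**Figure D1:**
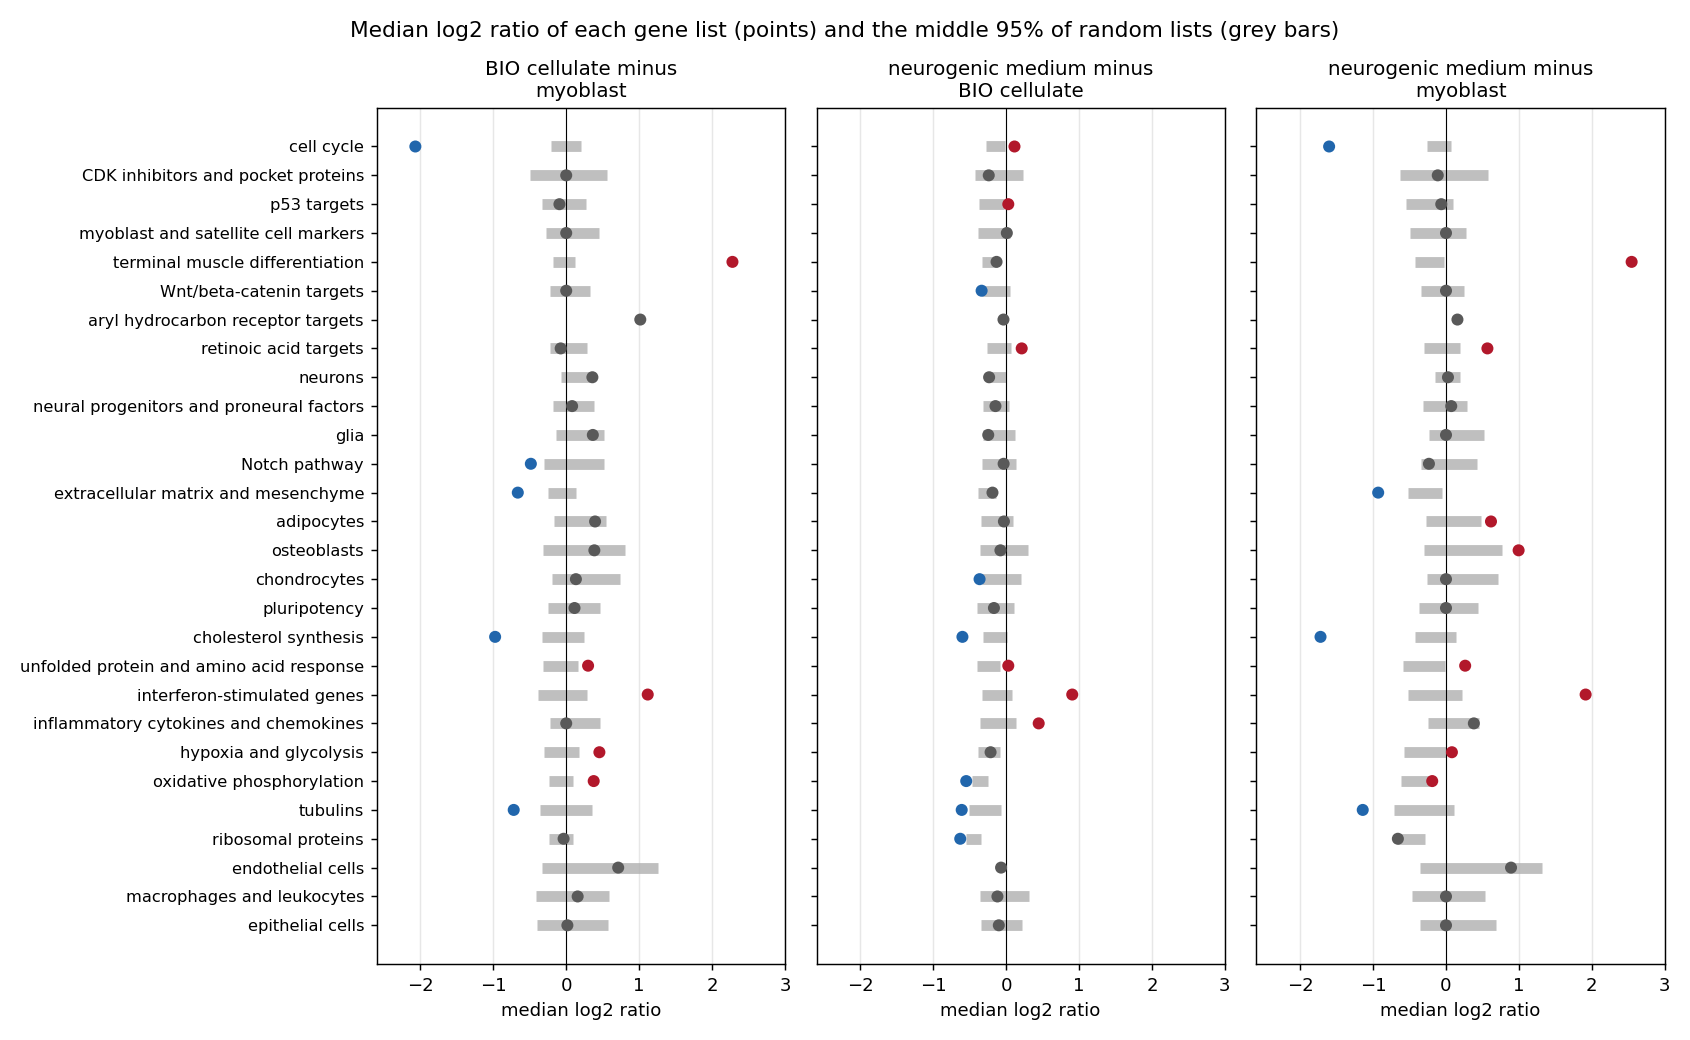
Median log2 ratio of each of 28 gene lists in the 3 comparisons (points, horizontal axis in log2 units), with grey bars for the middle 95% of 10000 random lists matched on mean signal (none for lists with fewer than 5 measured genes), and red or blue points for lists outside it. Terminal muscle genes reach 2.28 and 2.55 in both comparisons with myoblasts, where cell-cycle genes lie at -2.07 and -1.60; among the coloured points, those of the oxidative phosphorylation, hypoxia and unfolded protein response lists in both comparisons with myoblasts, of retinoic acid targets in neurogenic cellulates against myoblasts, of the Notch list in BIO cellulates against myoblasts, and of the Wnt, chondrocyte and cell-cycle lists between cellulates change sign under at least 1 other setting.

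The second comparison asked what 7 days in neurogenic medium, after reversine and with retinoic acid, added to BIO cellulates. Genes that answer to retinoic acid gave the largest differences, interferon-stimulated genes were higher again, and sterol synthesis genes were lower again. Cyp26b1, which encodes a retinoic acid hydroxylase, was 326-fold higher in neurogenic cellulates and Dhrs3, a retinaldehyde reductase gene, 116-fold higher. Terminal muscle genes and neuronal genes, with median log2 ratios of -0.13 and -0.23, lay inside the middle 95% of random lists. Of 12255 genes compared, 510 were at least 2-fold higher and 220 at least 2-fold lower, or 266 and 153 among genes measured on both arrays, and the median over all 12255 was -0.17.

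Retinoic acid targets had a median log2 ratio of 0.21 and a mean of 1.05, with 8 of 26 at least 2-fold higher and 0 lower. Besides Cyp26b1 and Dhrs3, the homeobox gene Hoxa5 was 5.48-fold higher and the receptor gene Rarb, whose 1 probe was dim on the other arrays, at least 2.17-fold. Cyp26a1, a further retinoic acid hydroxylase gene, was at least 1.35-fold higher. Interferon-stimulated genes had a median of 0.91, with 8 of 17 at least 2-fold higher, among them Isg15 (3.83-fold), Usp18 (3.42-fold) and the transcription factor gene Irf7 (2.53-fold). B2m, the light chain of MHC class I, was at least 12.3-fold higher, and neither of its probes was well above background on the other arrays. Inflammatory cytokine and chemokine genes had a median of 0.45, with 2 of 13 at least 2-fold higher, the acute-phase gene Saa3 (at least 10.1-fold, by a probe dim on the other arrays) and the chemokine gene Ccl7 (3.24-fold), and with Il1a at least 2.05-fold lower.

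Among the lower groups, cholesterol synthesis genes had a median of -0.60, with 4 of 22 at least 2-fold lower, including Cyp51 (2.73-fold), Idi1 (2.62-fold) and Fdps (2.55-fold). Ebp, a sterol isomerase gene chosen after its values were seen, was the 1 member at least 2-fold higher, with a bound of 1.09 on the log2 scale. Wnt and beta-catenin targets had a median of -0.34, or 0.013 when scaled on spike-in controls, and 4 of 18 were at least 2-fold lower: the Wnt antagonist genes Wif1 (4.71-fold) and Kremen1 (2.82-fold), Nkd2 (at least 4.74-fold) and Bmp4 (2.07-fold). This list returned inside the middle 95% when only genes measured on both arrays were compared or random lists were not matched. Lef1 had a log2 ratio of 0.59. Chondrocyte genes had a median of -0.36, or 0.011 with spike-in scaling, with Comp 2.04-fold lower among 10, and left the lower tail under 3 of 10 other settings. Tubulin genes had a median of -0.61, with 4 of 12 at least 2-fold lower, including Tuba4a (2.34-fold), Tubb4a (2.22-fold) and Tubb5 (2.07-fold), while the probe of Tuba1a was 13.3-fold higher.

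Ribosomal protein genes had a median log2 ratio of -0.63 and oxidative phosphorylation genes of -0.55, but single members of both lists were far higher, and the ribosomal list lay inside the middle 95% of random lists after quantile normalisation. Rps4x was 19.5-fold and Rpl14 2.82-fold higher among 47 ribosomal genes, none of which was at least 2-fold lower. Sdhd (at least 6.86-fold), Ndufb10 (6.21-fold) and Ndufs8 (at least 2.30-fold) were among 5 of 48 oxidative phosphorylation genes at least 2-fold higher, and Ndufb5 was at least 3.96-fold lower. Rpl41 (20.7-fold), Atpif1 (19.9-fold), Rpl39 (at least 35.4-fold), Ctsl (at least 22.5-fold) and Uqcr10 (at least 20.8-fold) were also among the largest differences. The probes of Rps4x, Rpl41 and Atpif1 were well above background on all 3 arrays, unlike the set counted next. On this array 105 of 2360 probes (4.45%) that were dim on both other arrays, in genes with a second and bright probe, were at least 4-fold brighter than on the BIO array, compared with 10 of 2249 (0.445%) that were brighter on the BIO array than on the myoblast array. The bright probes of the same 105 had a median log2 ratio of -0.21.

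Cell-cycle genes had a median of 0.12, which turned to -0.026 over the members well above background on both arrays, and 11 of 43 were at least 2-fold higher. The largest, Birc5 (at least 13.5-fold), the replication licensing genes Mcm4 (at least 7.99-fold) and Mcm5 (at least 5.71-fold), and Aurka (at least 5.31-fold), were not well above background in BIO cellulates. Mki67 had a log2 ratio of 0.80, Cdk1 of -0.09 and Cdkn1a of -0.28. The p53 target list and the unfolded protein and amino acid response list had medians of 0.03 each, above random lists (the p53 list not with the median over a gene's probes), with Gdf15 (2.74-fold) the 1 of 21 p53 targets and the asparagine synthetase gene Asns (2.33-fold) the 1 of 27 response genes at least 2-fold higher.

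Of 59 terminal muscle genes, 8 were at least 2-fold higher and 6 lower. The light chain genes Myl1 (9.05-fold) and Myl3 (6.25-fold) were higher, although the second probe of Myl3 gave a log2 ratio of 0.05, and the embryonic light chain gene Myl4 (4.46-fold) and cardiac troponin T gene Tnnt2 (3.71-fold) were lower. Myh3 had a log2 ratio of -0.99, Ckm of 0.22, Acta1 of -0.07, Myog of 0.82, Myod1 of -0.40 and Pax7 of -0.29. Of 33 neuronal genes, the neurofilament gene Nefm was at least 2.30-fold higher and the endosomal gene Nsg1 4.85-fold lower. Among 20 neural progenitor genes 0 differed by 2-fold. Map2 had a log2 ratio of 0.86, Tubb3 of -0.26, Nes of -0.34, Neurog1 of -0.35 and Gfap of -0.08.

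Other large differences included Inmt, a methyltransferase gene (31.0-fold higher), the chaperone gene clusterin Clu (23.6-fold higher) and Tmem59 (22.4-fold higher), which had been lower on the BIO array. The prostacyclin synthase gene Ptgis was 15.4-fold lower, Anxa8 6.67-fold, Chtf8 6.45-fold, Cables1 5.81-fold, Postn 5.58-fold, the smooth muscle gene Tagln 5.24-fold and the Notch ligand gene Dner 4.86-fold. Mtus2 (at least 5.24-fold), Prss46 (at least 5.20-fold) and Nol3 (at least 4.96-fold) were lower by bounds. Of the genes at least 2-fold different, 69.9% were higher, against 83.5% with the percentile over probes well above background, 92.6% with spike-in scaling, 62.5% with no filter on dim probes and 63.5% among genes measured on both arrays.

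Further members of small groups, chosen after their values were seen, had log2 ratios of -1.03 for Tubb2a (tubulins), and 1.14 for Cox6a1 and 1.12 for Cox6c (oxidative phosphorylation).

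**Figure D2:**
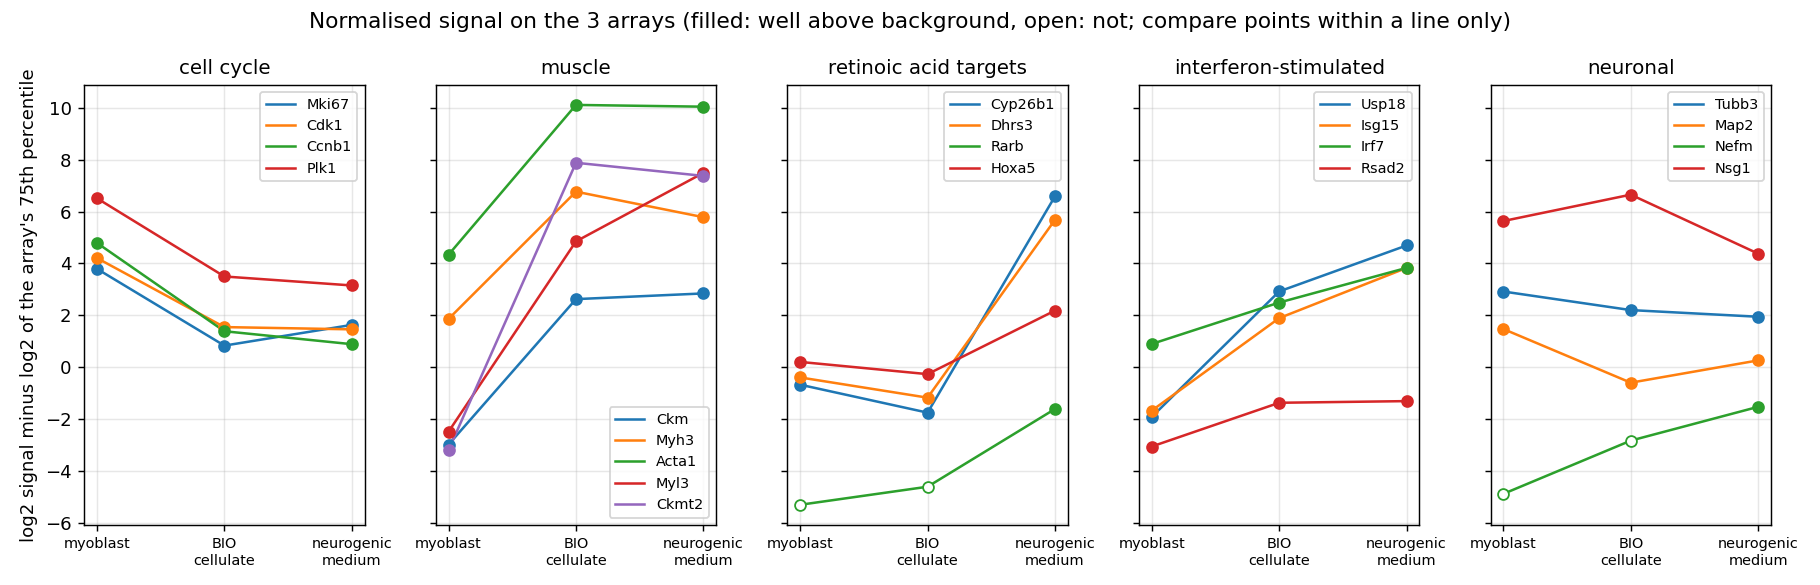
Signal of 21 named genes on the 3 arrays, as log2 signal minus the log2 of the array's 75th percentile (vertical axis); each line is 1 gene, filled points were well above background and open points were not, and points may be compared within a line but not between lines, since probes differ in brightness. Cyp26b1 and Dhrs3 stand apart on the neurogenic array, where Cyp26b1 was 326-fold above its signal on the BIO array, while Ckmt2 separates both cellulate cultures from myoblasts.

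The third comparison set the neurogenic cellulates against untreated myoblasts. Muscle genes and interferon-stimulated genes were higher, and sterol synthesis and cell-cycle genes were lower. Ckmt2 was 1530-fold higher than in myoblasts, Cyp26b1 154-fold higher and Usp18 98.1-fold higher. Anxa8 was 68.4-fold lower and Postn, a secreted matrix protein gene, 19.6-fold lower. Of 12855 genes compared, 1557 were at least 2-fold higher and 1291 at least 2-fold lower, or 1018 and 1199 among genes measured on both arrays.

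Terminal muscle genes had a median log2 ratio of 2.55, with 43 of 62 at least 2-fold higher. Tnnt3 was 77.8-fold higher, the slow troponin I gene Tnni1 71.7-fold, Ckm 57.0-fold, Acta1 52.4-fold and Myh3 15.2-fold. Myl3 was 1016-fold higher by its brighter probe, with a log2 ratio of 0.75 by its second probe. The cardiac actin gene Actc1, chosen after its values were seen, was the 1 member at least 2-fold lower, with a log2 ratio of -1.76. Mustn1 was 75.2-fold higher, Myo18b at least 181-fold, Abra, an activator of actin signalling, at least 90.1-fold and Ampd1 at least 73.6-fold. Myog was 2.18-fold higher, with log2 ratios of -0.03 for Myod1 and 0.44 for Pax7.

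Interferon-stimulated genes had a median of 1.92, with 14 of 17 at least 2-fold higher and 1 lower. Isg15 was 45.6-fold higher, Irf7 7.65-fold and B2m at least 24.6-fold. Oas1f, an oligoadenylate synthetase gene outside the list, was 137-fold higher. Leukocyte markers stood beside them with 2 of 9 at least 2-fold higher and a median of 0.00, or 0.30 with the median over a gene's probes. Over the 6 measured on both arrays, which leaves out markers detected on 1 array, the median was -0.18. Retinoic acid targets had a median of 0.57, or -0.11 with median scaling, with 9 of 26 at least 2-fold higher, including Dhrs3 (67.7-fold), Rarb (at least 4.34-fold) and Cyp26a1 (2.40-fold). The Cyp26a1 probe was near background on both arrays. Its log2 ratio of 1.26 was close to the median of 1.14 over the genes dim on both.

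Cell-cycle genes had a median of -1.60, with 29 of 46 at least 2-fold lower and 12 higher. Ccnb1 was 15.0-fold lower, the mitotic kinesin gene Kif20a 10.4-fold, Cdk1 6.73-fold and Mki67 4.48-fold. Mcm4 (at least 16.0-fold) and Aurka (at least 10.6-fold) were higher, and their probes were well above background on the neurogenic array alone. Cdkn1a had a log2 ratio of 0.44. The growth-promoting transcription factor gene Mycn was 15.2-fold lower.

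Cholesterol synthesis genes had a median of -1.72, or -0.91 with the median over a gene's probes. Of 24, 16 were at least 2-fold lower, among them Idi1 (9.03-fold), Dhcr7 (7.30-fold) and Fdps (6.25-fold). Ebp, chosen after its values were seen, was the 1 at least 2-fold higher, with a bound of 2.09 on the log2 scale. Extracellular matrix and mesenchyme genes had a median of -0.93, with 19 of 41 at least 2-fold lower and 6 higher. Thbs1 was 10.4-fold lower, Tagln 9.21-fold lower and Timp3 8.20-fold higher. Tubulin genes had a median of -1.14, with 8 of 12 at least 2-fold lower, including Tubb4a (3.96-fold), Tubb4b (3.93-fold) and Tubb5 (3.41-fold), and with Tuba1a, whose probe was brighter on the neurogenic array, 6.46-fold higher. Ptgis was 29.4-fold lower, the coiled-coil gene Ccdc88b 12.3-fold and the monoacylglycerol lipase gene Mgll 12.2-fold. Areg (at least 8.90-fold), Emp1 (at least 7.01-fold) and Gas2l3 (at least 6.09-fold) were lower by bounds.

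The unfolded protein and amino acid response list had a median of 0.26, which turned to -0.47 with median scaling and -0.031 after normexp correction, with 8 of 27 at least 2-fold higher and 4 lower. Atf3 was 6.19-fold higher, Asns 4.73-fold, Ddit3 4.62-fold and the serine synthesis gene Psat1 at least 3.35-fold. Hypoxia and glycolysis genes had a median of 0.08, or -0.65 with median scaling, and lost their place above unmatched random lists, with Vegfa (5.72-fold), Adm (4.97-fold), Hk2 (3.76-fold) and Ankrd37 (3.06-fold) higher and 2 of 26 at least 2-fold lower. Adipocyte genes had a median of 0.62, with 5 of 16 at least 2-fold higher, among them the transcription factor gene Cebpa (6.48-fold by its brighter probe, with a log2 ratio of 0.15 by its second probe, which was dim on the neurogenic array), the desaturase gene Scd1 (4.20-fold), the fatty acid transporter gene Cd36 (at least 3.72-fold) and the lipase gene Lipe (2.87-fold). Osteoblast genes had a median of 1.00, or 0.00 with the median over a gene's probes (-0.50 over the 5 measured on both arrays), and lay inside the middle 95% of random lists under 2 of 10 other settings, with 4 of 9 at least 2-fold higher, including Spp1 (at least 4.87-fold) and Pth1r (at least 4.02-fold). The osteoblast transcription factor gene Sp7 was at least 2.45-fold lower. Oxidative phosphorylation genes had a median of -0.19 but a mean of 0.16 and lay above matched but not above unmatched random lists, and the median turned to 0.31 after quantile normalisation. Of 46, 6 were at least 2-fold higher, including Cox6a2 (52.9-fold), Sdhd (6.83-fold), Ndufb10 (6.37-fold) and Ndufs8 (at least 4.60-fold).

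Neural groups lay inside the middle 95% of random lists. The median over 36 neuronal genes was 0.03, with 7 at least 2-fold higher and 5 lower. It was 0.26 over the 27 measured on both arrays, and 0.27 with the median over a gene's probes. Neural progenitor genes had 0.41 over the 18 measured on both, and 0.03 with the median over a gene's probes. Glial genes had 0.00, and 0.56 with the median over a gene's probes. Places of these lists among random lists are given for the main setting alone. The microtubule-associated gene Mapt was 6.94-fold higher, Nefm at least 4.60-fold and Vamp2 3.64-fold higher by its brightest probe, with log2 ratios of 1.61 and -0.44 by its other probes, and Dpysl3 was 4.49-fold and Map2 2.32-fold lower. Tubb3 had a log2 ratio of -0.97, Nes of 0.45, Neurog1 of -0.90, Gfap of 0.80 and Lef1 of -0.73. The Gfap probe was near background, and its ratio was below the median of 1.14 over genes dim on both arrays. Of the genes at least 2-fold different, 54.7% were higher than in myoblasts, against 11.5% with median scaling, 78.9% with the percentile over probes well above background, 82.1% with spike-in scaling, 31.4% after normexp correction, 76.9% with no filter on dim probes and 45.9% among genes measured on both arrays.

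Further members of small groups, chosen after their values were seen, had log2 ratios of 1.07 for Dgat2 and -1.51 for Fasn (adipocytes), 1.12 for Sost and -1.25 for Runx2 (osteoblasts), -1.24 for Xbp1, -1.13 for Creld2, -1.10 for Phgdh and -1.30 for Pdia4 (unfolded protein and amino acid response), and 1.16 for Slc2a1, -1.51 for P4ha2 and -1.36 for Eno1 (hypoxia and glycolysis).

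**Figure D3:**
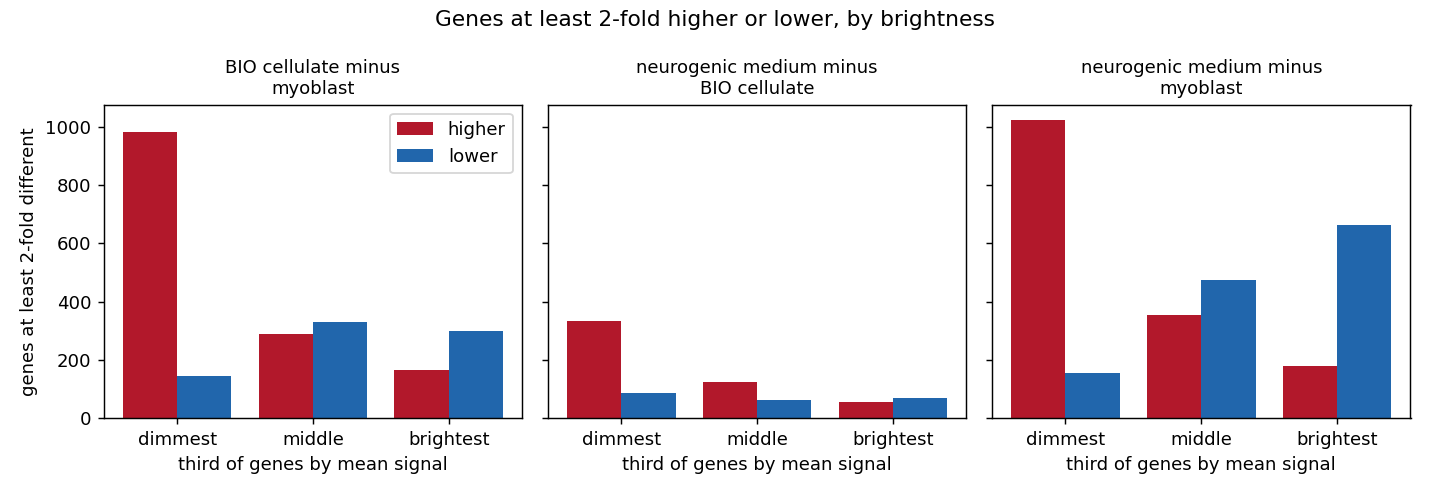
Number of genes at least 2-fold higher (red) or lower (blue) in each comparison, for 3 equal groups of genes ordered by mean signal from dimmest to brightest (vertical axis, genes). Among the dimmest genes 983 were higher and 144 lower in BIO cellulates than in myoblasts, and among the brightest 167 were higher and 298 lower.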

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

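All explanations weighed here were tested only after the pattern had been seen. Probes that could not be named carried signal outside the gene counts. Of 4562 unnamed probes compared, 877 (19.2%) were at least 2-fold higher in BIO cellulates than in myoblasts and 188 lower. Of 4357, 545 (12.5%) were at least 2-fold higher in neurogenic cellulates than in myoblasts and 284 lower.

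The first pattern is the set of probes that were dim on the myoblast and BIO arrays and at least 4-fold brighter on the neurogenic array. Among genes with a second, bright probe they numbered 105 of 2360 (4.45%), against 12 of 2591 (0.463%) for the same count on the myoblast array. For most of these genes, more RNA of the whole gene, from the cultures or from other mouse cells, is argued against by their bright probes, with a median log2 ratio of -0.21. For 8 of the 105 the bright probe was itself at least 2-fold higher, so it is not argued against there. Only genes with a probe well above background on all 3 arrays could enter, so genes switched on in neurogenic medium were not covered. A flaw of the slide surface is argued against by neighbouring spots, of which 1.94% were at least 4-fold brighter against 1.84% of all spots. A candidate explanation is labelled material copied from the same abundant transcripts in another form, such as the other strand or another transcript end, since such probes made up 7.75% in genes with the brightest partner probes and 3.18% in those with the dimmest, although with 2.42% in the middle group the share did not rise steadily. A change of transcript form in the cultures was not tested. All probes of Mcm4, Aurka, B2m, Ctsl, Psat1, Rarb, Saa3, Spp1 and Krt18 were dim on the other arrays. These genes had no bright second probe, so whether they share this pattern or had more RNA stays open.

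The second pattern is the excess of higher over lower genes in BIO cellulates against myoblasts, 65.1% of those at least 2-fold different. It was 87.2% among the dimmest of 3 equal groups of genes by mean signal and 35.9% among the brightest. The rule for bounds is part of this, since 497 of 498 genes measured on the BIO array alone passed 2-fold. Of those measured on the myoblast array alone, 85 of 1146 passed. Among genes measured on both arrays 57.9% of those at least 2-fold different were higher. Background that is a larger part of the signal on the BIO array could give the same split by brightness. The excess may therefore be technical, and the groups by brightness cannot tell background from the rule for bounds. A biological excess among weakly expressed genes was not tested and stays open.

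The third pattern is the higher signal of interferon-stimulated genes in neurogenic cellulates. A large amount of RNA from leukocytes or macrophages is argued against by their markers, since 2 of 11 that were dim in myoblasts (18.2%), Laptm5 and Spi1, were well above background on the neurogenic array. Spi1 was also well above background on the BIO array. A small amount could leave most markers dim, so these counts cannot exclude it. Probes dim on the other arrays do not account for the whole rise, since 15 interferon genes measured on all 3 arrays had a median log2 ratio against myoblasts of 1.91. The same 15 genes had a median of 1.02 in BIO cellulates against myoblasts. Brightening of probes that were measured on all 3 arrays, as seen for Rps4x, Rpl41 and Atpif1, is not covered by this. An interferon response of the cultures is a hypothesis that stays open, and these arrays cannot tell which step of the treatment it would follow. A difference between single cultures was not tested, since each group had 1 array.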

How the results depend on the processing

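Normexp on median signals and spike-in scaling were chosen after the data were seen, and the other settings before. No paired analysis was possible because each group has 1 array, which also leaves no array to leave out. Normexp on mean spot signals was not run, since that column is not used here. Of 117 alternative counts, 88 lay within 1.5 times of the reported count, and of 340 alternative medians of called lists, 327 kept their call and 14 turned sign. With the authors' values no count moved that far and no list turned. Those values are the same intensities plus constants close to the scaling used here, so this is no independent check.

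Below, the first comparison is BIO cellulates against myoblasts, the second neurogenic against BIO cellulates and the third neurogenic cellulates against myoblasts, with higher counts before lower. Scaling to the array median moved the median of all genes by -0.66 and -0.73 in the first and the third comparisons and gave 369 and 3701 genes in the first and 649 and 4997 in the third. It turned unfolded protein (-0.42), hypoxia (-0.26) and oxidative phosphorylation (-0.34) genes in the first, and retinoic acid (-0.11), unfolded protein (-0.47) and hypoxia (-0.65) genes in the third, all still above random lists. These signs follow from the shift itself, and so do the kept places, since the random lists shift too. The array medians lay near the lowest signals well above background, so median scaling rests on signal near background. The percentile over probes well above background moved the medians by 0.13, 0.17 and 0.18, gave 136 lower genes in the second and 620 in the third, and turned oxidative phosphorylation in the third (0.16). Quantile normalisation gave 820 higher genes in the first and turned oxidative phosphorylation in the third (0.31). Spike-in scaling moved the medians by 0.36 and 0.24 in the second and the third, gave 995 and 79 genes in the second and 2511 and 548 in the third, and turned Wnt targets (0.013) and chondrocytes (0.011) in the second and oxidative phosphorylation (0.22) in the third. Normexp gave 301 higher genes in the first, 200 and 70 in the second and 527 higher in the third, turned the unfolded protein list in the third (-0.031), and left 69 of 105 genes taken by the naming rule at least 2-fold different in the first. Its offset draws dim signals together.

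Without the dim-probe filter, 4385 genes were higher in the first, 1032 and 619 in the second and 5118 higher in the third, with more genes compared, the median moved by 0.27 and 0.24 in the first and the third, and the Notch list turned in the first (0.008). With genes measured on both arrays alone, 943, 266 and 1018 were higher, since bounds drop out, and the cell-cycle list turned in the second (-0.026). The median over probes turned Lpl in the second (0.26), whose other probe was dim on the BIO array. With that setting cholesterol synthesis genes had smaller medians of -0.67, -0.38 and -0.91 in the 3 comparisons. Cell-cycle genes had -1.36 in the first and -1.05 in the third. At 3-fold there were 484 and 243, 227 and 48, and 778 and 419 genes, and the higher share was 82.5% in the second and 65.0% in the third. Where no reason is given, the cause was not tested. Signal near background limits folds of dim genes, and bounds replace them.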

Other observations

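No explanation was tested in this part. Medians marked as measured on both leave out genes measured on 1 array, which have bounds or no fold. Gene groups beyond those described in the report mostly lay inside the middle 95% of random lists. In BIO cellulates against myoblasts the muscle integrin gene Itga7 was 5.72-fold higher, while the satellite cell receptor gene Megf10 was at least 6.77-fold lower and the cadherin gene Cdh15 2.15-fold lower. The median log2 ratio over 12 myoblast and satellite cell markers measured on both was 0.08. In neurogenic against BIO cellulates the adhesion gene Vcam1 (6.85-fold) and Itga7 (2.30-fold) were higher and the median over 13 markers was 0.01. In neurogenic cellulates against myoblasts the median over 13 markers measured on both was 0.11, with Itga7 13.1-fold and Vcam1 10.1-fold higher. CDK inhibitors and pocket proteins had medians of -0.57, -0.24 and -0.54 in the 3 comparisons, each over 5 measured on both. Over all 7 measured the medians were 0.00, -0.24 and -0.11. Among them, Rbl2 was at least 3.11-fold higher and Rbl1 (2.98-fold) and Cdkn2c (2.97-fold) lower in BIO cellulates than in myoblasts. Cdkn2b was at least 3.94-fold higher in neurogenic cellulates than in myoblasts. The p53 targets had a median of -0.09 in the first comparison and -0.07 in the third. Among them Eda2r was 5.25-fold and 7.19-fold higher, by a probe near background in myoblasts. Inflammatory genes had a median of 0.41 (10 measured on both) in the first and 0.38 in the third, with Ccl7 9.68-fold and 31.4-fold higher. The interleukin gene Il6 was 2.92-fold and 3.99-fold higher, and Saa3 at least 21.9-fold higher in the third.

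Among other lineages, adipocyte genes had medians of 0.40 in the first and -0.03 in the second comparison, where Lpl was 3.18-fold lower by its brightest probe and its other probe was dim on the myoblast and BIO arrays. Osteoblast genes had medians of 0.39 and -0.08, with Runx2 3.21-fold lower in the first. Chondrocyte genes had medians of 0.13 in the first and -0.07 (9 measured on both) in the third, where Comp was 7.06-fold lower. Glial genes had medians of 0.37, -0.25 and 0.32 (the last over 13 measured on both), with the folate enzyme gene Aldh1l1 4.75-fold and the myelin gene Pmp22 3.44-fold higher in neurogenic cellulates than in myoblasts. Neural progenitor genes had medians of 0.08, -0.15 and 0.07, or 0.50, -0.15 and 0.41 over those measured on both. The Notch ligand gene Dll1 was 5.12-fold higher and Sox11 3.97-fold lower in the third. Notch genes had medians of -0.03 and -0.23 in the second and the third, with Hes1 2.18-fold higher in the second. Retinoic acid targets had a median of -0.08 in the first, where Cyp26b1 was 2.11-fold lower. Wnt targets had a median of -0.73 (15 measured on both) in the third, with Wif1 6.88-fold lower and Rnf43 4.28-fold higher. Pluripotency genes had medians of 0.11, -0.17 and 0.20 (the last over 9 measured on both), with Zfp42 at least 4.24-fold lower in the first. Matrix genes had a median of -0.19 in the second, with decorin Dcn 6.47-fold higher, and hypoxia genes of -0.21, with Adm 2.23-fold higher. Ribosomal protein genes had medians of -0.04 in the first and -0.66 in the third. Aryl hydrocarbon receptor targets, with 4 measured, had medians of 1.02, -0.04 and 0.16, and Gsta1 was 17.1-fold higher in the third. Endothelial genes had medians of 0.71 and 0.89 in the first and the third, leukocyte genes of 0.16, -0.12 and -0.18 (the last over 6 measured on both), and epithelial genes of 0.02, -0.10 and -0.27 (the last over 8 measured on both), with Krt18 at least 7.28-fold higher in the third. Endothelial genes in the second comparison, with 4 measured, had a median of -0.07.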
